A study of Mus musculus with 10 samples.

How the data were processed

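Gene-level tables of 10 mouse RNA-seq libraries were used, 1 table per library. Per the labels, RNA was extracted from sorted LT-HSCs with an RNeasy Micro kit and libraries were made with a stranded total RNA kit for picogram inputs (SMARTer Stranded Total RNA-Seq, version 2, Pico). The submitters' processing notes name STAR 2.5.2b, an aligner, RSEM 1.3.0, which estimates read counts per gene, and the build mm10, without giving their order or settings. Trimming, removal of duplicate reads and the strand setting are not given in the sources used here, so genes that overlap on opposite strands are uncertain. The deposited tables give an expected count per gene, per the file headers in the layout of RSEM, which shares reads that match several genes between them, so levels of near-identical genes are uncertain. The authors also deposited TPM (transcript abundances scaled to a fixed total), per the file headers, which sum to the same total in each table and keep no depth. Of the expected counts, 1.24% to 2.7% per library were not whole by more than 1e-06, and all were rounded to whole numbers before any count test.

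The tables of males list 55487 genes and those of females 53918. The 1569 genes listed for males alone, of which 1562 lie on chromosome Y in the reference annotation (GENCODE M21, GRCm38, the same assembly as mm10), were left out of the tests and enter as 0 in an alternative. Gene symbols and coordinates came from this annotation, in which 55094 identifiers matched exactly, 300 matched without their version and 93 did not match. Total counts per library over the shared genes were 14315066 to 32851650, which gives a gene at 10 CPM over 100 counts in every library. Read counting error was therefore small at such levels beside the spread between libraries. Sequenced copies made by PCR are not independent molecules, and the counts carry no molecular identifiers. Loss of molecules before sequencing can thus be part of that spread. The libraries were compared pair by pair for duplicates with a chi-square per gene. Labels name the same sequencing lane for all libraries and give no other batch.

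Groups were taken from the genotype labels and sex from the gender labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM normalisation, filterByExpr by genotype (minimum count 10, minimum total 15), a quasi-likelihood F test with sex and genotype as terms, and Benjamini-Hochberg adjustment over 13943 genes with a threshold of 0.05. The sex term of the same fit compared females with males, and a fit with a sex by genotype term tested the interaction. Levels are TMM-normalised CPM (a gene's count scaled to a fixed library total), means ± SD over libraries, and confidence intervals are at 95%. Gene lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01, the same terms, at least 5 tested members and adjustment over the 29 lists. Camera with an estimated correlation and fry were run beside it. A list's level is the mean log2 CPM of its tested members. Members of each list were also adjusted over the list alone. Camera compares a list with other genes, and fry tests whether its genes move, on balance, one way.

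The design, the alternatives, the lists and the rule for named genes were written before the data were examined. The lists were long-term HSC genes, heptad transcription factors, GATA2-linked genes, the ETS family, neighbours of Gata2, neutrophil precursor and granule genes, monocyte and dendritic cell genes, megakaryocyte and platelet genes, erythroid genes, mast cell, basophil and eosinophil genes, lymphoid priming genes, B cell genes, T and NK cell genes, endothelial and stromal genes, G2/M genes, S phase genes, quiescence and cell cycle inhibitor genes, interferon response genes, NF-kB and cytokine genes, immediate early and dissociation genes, p53 target genes, nuclear-encoded oxidative phosphorylation genes, glycolysis genes, cholesterol synthesis genes, cytosolic ribosomal protein genes, unfolded protein response genes, TGF-beta and BMP pathway genes, replication-dependent histone genes and mitochondrially encoded genes. They were put together from general knowledge, and some genes stand on more than 1 list. Named genes are Gata2; up to 12 genes per direction past the threshold or, where fewer pass, the 6 per direction with the smallest unadjusted p, without clone names and pseudogenes; up to 4 members per list with the smallest p and, for lists of other cell types, the 2 most abundant; the sex-linked genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty; 5 genes for the interaction; and neighbours of Gata2 with an unadjusted p under 0.05. Genes named outside this rule are said to have been chosen after their values were seen.

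Alternatives mostly changed 1 choice at a time. They were relative log expression size factors, no expression filter, and a stricter filter (1 CPM and 10 counts in at least 5 libraries). Others were DESeq2 1.42.0, limma-voom with and without quality weights, limma on log2(TPM + 1), and no structural RNA or mitochondrial genes. Further fits took genes absent from the tables of females as 0, added 1 surrogate variable (sva 3.50.0) or dropped the sex term. The last used each sex alone or left out each library in turn. DESeq2 also changed the size factors, limma on log2(TPM + 1) the scaling, and each sex alone dropped the sex term. After seeing the data, the levels of the neutrophil and monocyte lists were added as covariates. The fits were tested on simulated data for CH against WT, with 13305 genes at the dispersion trend of these libraries. Changed were 200 genes with a mean of at least 10 CPM. Of those changed 2-fold 19.4% were recovered, of those changed 4-fold 71.6% and of those changed 8-fold 93.9%, with 6 false calls. Genes were simulated independently and without a library that stands apart, so the real libraries may give lower rates. Other splits of the libraries were refitted with fixed seeds, 100 for genotype and 60 for sex, of 126 possible. Splicing, reads outside genes and the enhancer sequence were not analysed here.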

Results

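RNA was sequenced from long-term haematopoietic stem cells (LT-HSCs), the rare bone marrow cells that can replace the whole blood system, of wild-type (WT) and CH mice. CH mice carry a mutation on both alleles of the +9.5 enhancer of Gata2, a regulatory element inside the gene for GATA2, a transcription factor needed for stem cells to form and persist. Per the labels, 500 to 2000 cells per sample were sorted as lineage-negative, Sca1-positive, Kit-positive, CD150-positive and CD34-negative cells from C57BL/6 mice of 8 to 16 weeks. There were 10 libraries, 5 of each genotype. WT replicates 1, 3 and 4 and CH replicates 1 and 4 came from males, and WT replicates 2 and 5 and CH replicates 2, 3 and 5 from females. The replicate numbers only name the libraries. The labels do not tie each library to a separate animal in so many words, so the p-values measure the spread between these libraries.

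The estimated read counts over genes listed in every file summed to 14315066 in WT replicate 1, 29819881 in WT replicate 2, 32851650 in WT replicate 3, 30346380 in WT replicate 4 and 32512842 in WT replicate 5. In CH replicates 1 to 5 the totals were 31473877, 31487890, 32025240, 24439697 and 25001380. WT replicate 1 stood apart in more than depth. It had 11223 detected genes, against 13819 to 15983 in the other libraries, and it lay at -294.1 on the first principal component, which held 41.5% of the variance, against 12.2 to 51 for the others. Correlations between pairs of libraries ran from 0.71 to 0.9, and the lowest was 0.82 without WT replicate 1. Mitochondrial ribosomal RNA took 5.62% to 7.94% of the counts. No pair of libraries was alike within sampling noise: the lowest chi-square per gene over the pairs was 79.3, where 1 would mean sampling noise alone.

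Gata2 itself was measured first, since the mutated enhancer belongs to it. The gene (ENSMUSG00000015053.14) lies on chromosome 6 from 88193891 to 88207032 on the plus strand of mm10. Its normalised level was 362, 301, 145, 130 and 166 CPM (counts scaled to the library's normalised total) in WT replicates 1 to 5 and 317, 290, 161, 222 and 271 CPM in CH replicates 1 to 5. The means were 221 ± 104 CPM in WT and 252 ± 61.9 CPM in CH (SD, n = 5 each). The log2 fold change of CH against WT was 0.20 (SE 0.31, 95% confidence interval -0.49 to 0.88) and did not pass edgeR's quasi-likelihood test (adjusted p = 0.9998). A fall below -0.49 on the log2 scale therefore lay outside the interval, for the RNA of the whole libraries. Gata2 was lowest in WT replicate 4, WT replicate 3 and CH replicate 3. These held the most Ngp, a neutrophil granule gene, at 15317, 9769 and 11542 CPM. RNA of other cells can thus have part in the Gata2 levels, and the interval does not bound a fall within stem cells alone. WT replicate 1, the library that stood apart, held the highest Gata2 level, and without it the log2 fold change was 0.46. Leaving out another single library gave 0.05 (without CH replicate 1) to 0.42 (without WT replicate 2), and females alone gave 0.04. The enhancer's own sequence is not covered by gene-level counts, so the mutation itself was not seen in these values.

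**Figure D1:**
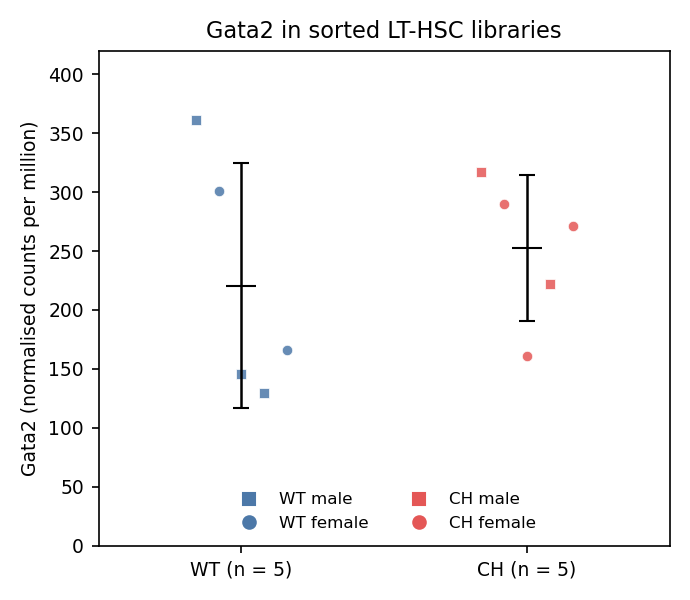
Gata2 level of each library, in normalised CPM, for WT and CH (squares are males, circles are females, black bars are means with 1 SD, n = 5 each). The WT libraries span 130 to 362 CPM and the CH libraries 161 to 317 CPM, so the genotypes overlap.

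The comparison of CH with WT asks which genes of sorted stem cells differ in animals with the mutated enhancer. Among the genes with the smallest unadjusted p, Bcl2, which codes for an inhibitor of cell death, was measured at 48.9 ± 6.81 CPM in WT and 88.7 ± 14.1 CPM in CH (SD, n = 5 each), with every CH library above every WT library. Slamf1, which codes for the sorting antigen CD150, was at 8.71 ± 3.29 CPM in WT and 27.2 ± 5.58 CPM in CH, again without overlap. In the other direction Myh10, a non-muscle myosin heavy chain gene, was at 186 ± 27.7 CPM in WT and 103 ± 40.5 CPM in CH. Rian, a maternally expressed non-coding RNA of an imprinted cluster, was at 13.1 ± 15.1 CPM in WT and 0.089 ± 0.199 CPM in CH, with 1410 counts over the WT libraries and 14 over the CH libraries. None of these genes passed the adjustment over all genes.

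Of 13943 genes tested with edgeR's quasi-likelihood test, 0 were higher and 0 were lower in CH at an adjusted p under 0.05, and the lowest adjusted p was 0.978. An unadjusted p under 0.05 was reached by 272 genes, 126 higher and 146 lower in CH. Evenly spread p-values would give 697, but other splits of these libraries gave a median of 290. DESeq2 called 3 genes higher and 5 lower with 470 genes at an unadjusted p under 0.05, limma-voom called 0 with 407, limma-voom with quality weights 0 with 701, and limma on log2(TPM + 1) called 1 with 434. With a library left out edgeR called 0 genes, with 445 at an unadjusted p under 0.05 without WT replicate 1 and 150 without CH replicate 1. The spread between libraries was wide, with a common biological coefficient of variation of 0.79. In 113 genes (73 higher and 40 lower in CH) the libraries of the genotypes did not overlap. That is 0.81% of the genes tested, and chance alone gives 0.794%, or 111 genes.

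The 6 named genes higher in CH did not pass in edgeR and did not overlap between the genotypes. Bcl2 (ENSMUSG00000057329.7, chromosome 1, 106538178 to 106714274) had a log2 fold change of 0.86 (SE 0.17, 95% confidence interval 0.49 to 1.24), and DESeq2 gave 0.84 with an adjusted p = 0.0479. Slamf1 (ENSMUSG00000015316.11, chromosome 1, 171767127 to 171801184) had a log2 fold change of 1.60 (SE 0.35), and DESeq2 gave 1.58 with an adjusted p = 0.0343. Slfn9, of the Schlafen family, was at 63.9 ± 15.7 CPM in WT and 132 ± 36.5 CPM in CH. Runx3, a transcription factor gene of the RUNX family, was at 59.8 ± 5.33 and 98.8 ± 30.9 CPM, and Tgfb1, the gene for the growth factor TGF-beta 1, at 104 ± 15.1 and 146 ± 16.7 CPM. Iglv1, an immunoglobulin lambda variable segment used by B cells, was at 1.93 ± 2.22 CPM in WT and 27.5 ± 20.6 CPM in CH (DESeq2 adjusted p = 0.00278). Reads of Slfn9 and Iglv1 can be shared with related genes, so these levels are uncertain.

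Among the 6 named genes lower in CH, all except Tnks1bp1 had no overlap between the genotypes, and none passed in edgeR. Myh10 (ENSMUSG00000020900.15, chromosome 11, 68691559 to 68816632) had a log2 fold change of -1.08 (SE 0.18, 95% confidence interval -1.47 to -0.69) and an adjusted p = 8.01e-05 in DESeq2. Rian (ENSMUSG00000097451.11, chromosome 12, 109603940 to 109661716) had a fitted log2 fold change of -7.30 (SE 1.28) and a DESeq2 adjusted p = 5.04e-07. WT replicate 1 held 39.6 CPM of Rian and the other WT libraries 2.36 to 10.4 CPM, and 4 of the 5 CH libraries had 0 counts. Wdfy1, which codes for an endosomal protein, was at 62.9 ± 3.45 CPM in WT and 26.4 ± 12.1 CPM in CH (DESeq2 adjusted p = 0.0343), with CH replicate 1 at 47.5 CPM and the other CH libraries at 18.3 to 25.1 CPM. Prdm16, a transcriptional regulator needed for stem cell maintenance, was at 63.7 ± 28.8 and 30.2 ± 4.95 CPM. Gipc3 was at 8.46 ± 3.13 and 1.66 ± 0.9 CPM and Tnks1bp1 at 66.5 ± 15.9 and 38.0 ± 12.6 CPM. DESeq2 also called Plxna2 (adjusted p = 0.0479) and Plekhg6 (adjusted p = 0.0479) lower, and limma on log2(TPM + 1) called Gm4489 higher (adjusted p = 0.0381). These 3 were named after their values were seen.

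**Figure D2:**
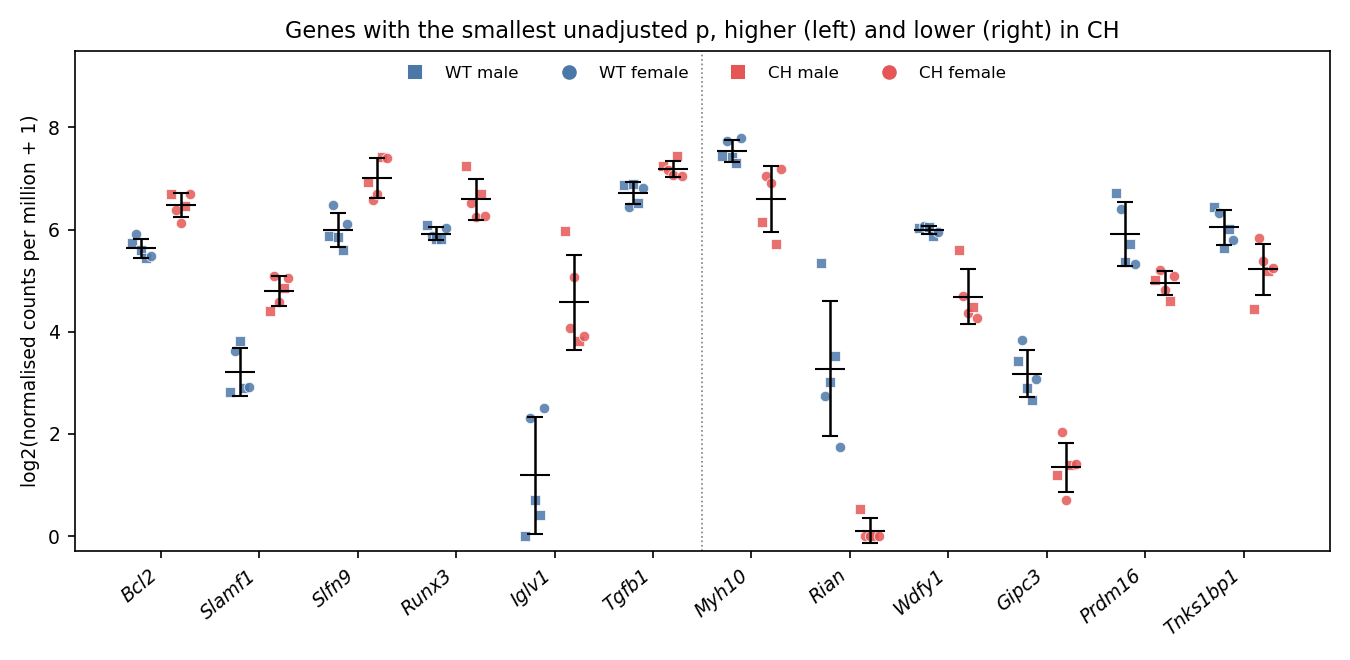
Level of the 6 genes with the smallest unadjusted p in each direction, as log2(normalised CPM + 1), in the WT libraries (blue) and CH libraries (red), with squares for males, circles for females and black bars for the mean with 1 SD (n = 5 each). All except Tnks1bp1 show no overlap between the genotypes, and none had an adjusted p under 0.05 in edgeR.

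Gene lists fixed in advance were compared next with limma's camera test, which asks whether the members of a list shifted more than other genes. With a preset correlation of 0.01 between genes, 9 of 29 lists were called at an adjusted p under 0.05. Other splits of the libraries called a median of 7 lists, and at most 16, in the same way. With the correlation estimated from the data camera called 0, and limma's fry test called 0. The estimates for the 9 called lists ran from 0.06 (quiescence genes) to 0.33 (erythroid genes). They were 0.83 for the neutrophil and G2/M lists. Where genes of a list move together more than the preset allows, the p-values at the preset are too small. No member of any list passed edgeR's test over all genes, and DESeq2 called 1 listed gene, Slamf1. With p-values adjusted over the list alone, edgeR called 1 member of the long-term HSC list (Slamf1, adjusted p = 0.0256) and 0 members of each of the other 28 lists.

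Genes that mark long-term stem cells were lower in CH as a list, although Slamf1 among them was higher (camera adjusted p = 2.22e-05, or adjusted p = 0.676 with an estimated correlation). Of 35 members 27 were lower, with a median log2 fold change of -0.42 and 7 members (1 higher and 6 lower) at an unadjusted p under 0.05. The mean level of the list was 4.53 ± 0.32 log2 CPM in WT and 4.11 ± 0.37 in CH (SD, n = 5 each), and WT replicate 1 had the highest level of all libraries, 4.95. Mmrn1, which codes for an extracellular multimerin protein, was at 170 ± 89.5 CPM in WT and 60.8 ± 32.0 CPM in CH, Prdm16 had a log2 fold change of -1.09 (SE 0.31), and Ndn, the gene of the imprinted growth suppressor necdin, had a log2 fold change of -1.96 (SE 0.71). Over 24 alternatives the camera adjusted p ran from 2.82e-09 to 0.278, and the call was lost with voom quality weights (adjusted p = 0.135) and in females alone (adjusted p = 0.278). Without WT replicate 1 the median was -0.24 and without WT replicate 5 it was -0.64. It was -0.22 with voom quality weights, -0.24 with 1 surrogate variable and -0.74 in males alone. In 54 of 100 splits of the 10 libraries into 5 and 5, the real one included, camera at the preset correlation called this list.

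Lists built around GATA2 showed no call. Among 7 transcription factors of the heptad that is bound together at blood stem cell enhancers, 3 were higher and 4 lower (camera adjusted p = 0.942), with a median log2 fold change of -0.05. Fli1, an ETS family factor gene of the heptad, was at 168 ± 25.1 CPM in WT and 191 ± 19.4 CPM in CH (SD, n = 5 each), Runx1, a regulator of stem cell emergence, at 131 ± 22.0 and 141 ± 20.8 CPM (with the opposite sign in females alone), and Lyl1 at 50.4 ± 17.5 and 41.6 ± 7.65 CPM. Of 27 genes linked to GATA2, 11 were higher and 16 lower (adjusted p = 0.54 with camera). Their median of -0.11 and camera's direction were negative while their mean log2 fold change was 0.08, and the list level was 4.52 log2 CPM in WT replicate 1 against 5.04 to 5.69 in the other WT libraries. Pf4, a platelet chemokine gene and the single member at an unadjusted p under 0.05, had a log2 fold change of 2.31 (SE 0.86). Kit, the stem cell factor receptor gene and a GATA2 target used in the sort, was at 409 ± 147 CPM in WT and 321 ± 71.3 CPM in CH, and Grb10, an imprinted adaptor gene, at 122 ± 42.1 and 83.8 ± 32.1 CPM. Among 16 ETS family genes 10 were higher and 6 lower (camera adjusted p = 0.54), and WT replicate 1 had the lowest list level, 5.8 log2 CPM.

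Genes that lie near Gata2 were also compared, since a mutated enhancer can act on its surroundings. Of 19 tested members 13 were higher and 6 lower, with a median log2 fold change of 0.16 (camera adjusted p = 0.0882, or adjusted p = 0.676 with an estimated correlation). Rpn1, which codes for a subunit of the enzyme that adds sugar chains to proteins, starts at 88084482 on chromosome 6 and was at 355 ± 38.8 CPM in WT and 491 ± 50.9 CPM in CH (SD, n = 5 each) without overlap, but did not pass in edgeR. Mcm2, a subunit of the replicative helicase, was at 187 ± 8.09 and 218 ± 23.2 CPM, and Copg1, of the vesicle coat, at 107 ± 5.02 and 120 ± 10.3 CPM. Acad9 was placed on the list from its position in human and lies on chromosome 3 in the mouse. It was at 31.4 ± 4.54 and 37.7 ± 4.42 CPM, with the opposite sign on log2(TPM + 1). The 13 higher members and the camera values of this list include Acad9. Over 24 alternatives the camera adjusted p of this list ran from 0.0128 to 0.752, and 7 of them called it, among them the fits without WT replicate 1 (adjusted p = 0.0223) and without CH replicate 1 (adjusted p = 0.0289).

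Markers of platelets and their precursors, the megakaryocytes, were higher in CH as a list. Of 24 tested members 18 were higher and 6 lower, with a median log2 fold change of 0.50 (camera adjusted p = 0.0119, or adjusted p = 0.676 with an estimated correlation) and 3 members (2 higher and 1 lower) at an unadjusted p under 0.05. Pf4 was at 11.1 ± 11.2 CPM in WT and 57.0 ± 27.9 CPM in CH (SD, n = 5 each), and Itga2b, the gene for the platelet integrin CD41, had a log2 fold change of 1.28 (SE 0.40). WT replicate 2 held 92.9 CPM of Itga2b and the other WT libraries 15.4 to 35 CPM. Trpc6 went the other way at 40.9 ± 17.6 and 23.8 ± 12.8 CPM, and the abundant Zfpm1 and Nfe2 had log2 fold changes of -0.01 (SE 0.24) and 0.18 (SE 0.13). The sign for Zfpm1 turned under several settings. The call was lost without WT replicate 5 (adjusted p = 0.264), CH replicate 1 (adjusted p = 0.0632) or CH replicate 3 (adjusted p = 0.152) and in males alone (adjusted p = 0.803), within a range of 1.17e-06 to 0.803 over the alternatives. The median was 0.33 without WT replicate 4, 0.25 without WT replicate 5 or CH replicate 1, 0.24 without CH replicate 3 and 0.29 in males alone.

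Erythroid genes were lower in CH by camera, while their mean level was not. Of 28 members 19 were lower and 9 higher, 4 of the lower members had an unadjusted p under 0.05, and the median log2 fold change was -0.38 (camera adjusted p = 0.0332, or adjusted p = 0.855 with an estimated correlation). The mean level was 4.23 ± 1.17 log2 CPM in WT and 4.35 ± 0.44 in CH, the opposite sign, with WT replicate 1 at 2.47. Tspan33, a tetraspanin gene of red cell precursors, was at 14.6 ± 6.21 CPM in WT and 4.32 ± 1.39 CPM in CH (SD, n = 5 each), with WT replicate 2 at 3.66 CPM. The transferrin receptor gene Tfrc was at 142 ± 14.6 and 96.7 ± 34.4 CPM, the membrane skeleton gene Ank1 at 116 ± 31.0 and 66.8 ± 39.6 CPM, and the abundant carbonic anhydrase genes Car2 and Car1 at 615 ± 108 and 520 ± 174 CPM and at 193 ± 34.5 and 141 ± 69.8 CPM. The sign for Car2 turned in females alone. Camera no longer called the list without WT replicate 3 (adjusted p = 0.167), WT replicate 4 (adjusted p = 0.264), WT replicate 5 (adjusted p = 0.364), CH replicate 2 (adjusted p = 0.116) or CH replicate 4 (adjusted p = 0.433), without the sex term (adjusted p = 0.133) and without an expression filter (adjusted p = 0.0746), and in females alone the direction turned (adjusted p = 0.856). These values lie in a range of 1.02e-05 to 0.856. Their median was -0.10 without CH replicate 4, -0.17 without WT replicate 4, -0.19 without WT replicate 5 and -0.65 without WT replicate 2. It was also -0.25 with voom, -0.23 on log2(TPM + 1), -0.19 without the sex term, -0.74 in males alone and -0.03 in females alone.

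Markers of other mature blood cells, which the sort should leave out, were not called over all libraries and were lowest in WT replicate 1. Among 30 genes of neutrophil precursors and granules 12 were higher and 18 lower (camera adjusted p = 0.145, or adjusted p = 0.907 with an estimated correlation), the median log2 fold change of -0.03 and the upward direction of camera differing in sign. The abundant granule genes Ngp and Ltf were at 6844 ± 5843 and 3515 ± 2830 CPM in WT and at 6124 ± 3193 and 2975 ± 1427 CPM in CH (SD, n = 5 each). The level of this list was 2.2 log2 CPM in WT replicate 1 and 5.84 to 7.88 in the other WT libraries. Of 26 monocyte and dendritic cell genes 16 were higher and 10 lower (camera adjusted p = 0.881), with 2.28 log2 CPM in WT replicate 1 and 5.23 to 7.52 in the other WT libraries. Lyz2, the lysozyme gene, was at 1646 ± 1204 and 1501 ± 773 CPM, Apoe, a macrophage lipid carrier gene, at 1265 ± 1058 and 1685 ± 1351 CPM, and H2-Aa, of the antigen presenting complex, at 71.4 ± 25.5 and 39.7 ± 4.72 CPM. The signs of Ngp, Ltf, Lyz2 and Apoe turned between settings. Camera called the neutrophil list higher without WT replicate 3 (adjusted p = 0.0207), WT replicate 4 (adjusted p = 0.0012) or CH replicate 2 (adjusted p = 0.036). It did so too in females alone (adjusted p = 4.12e-06, median 0.74, with -0.83 in males alone), in a range up to 0.894. The interaction with sex had an adjusted p = 0.0747 for this list (adjusted p = 0.916 with an estimated correlation) and, without WT replicate 1, an adjusted p = 1.29e-13 (adjusted p = 0.557 with an estimated correlation). With a library left out its median ran from -0.43 (WT replicate 2) to 0.33 (WT replicate 4), and that of the monocyte list from -0.50 (CH replicate 4) to 0.68 (WT replicate 5). Camera called the monocyte list lower without WT replicate 1 (adjusted p = 0.0262, median -0.12), with 1 surrogate variable (adjusted p = 0.0259) and with voom quality weights (adjusted p = 0.000869), in a range up to 0.978.

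Among 22 B cell genes 5 were higher and 17 lower, with a median log2 fold change of -0.63 (camera adjusted p = 0.205), and the list level in WT replicate 1 was 1.85 log2 CPM against 4.17 to 5.58 in the other WT libraries. The abundant antibody genes Ighm and Igkc went against the median, at 2646 ± 2556 and 1034 ± 836 CPM in WT and at 6150 ± 5464 and 2606 ± 2698 CPM in CH (SD, n = 5 each), and Ms4a1, the gene for CD20, was at 31.4 ± 10.2 and 17.7 ± 8.83 CPM. Of 26 lymphoid priming genes 6 were higher and 20 lower (camera adjusted p = 0.157), with a median of -0.35 and a level of 3.1 log2 CPM in WT replicate 1. Of 12 T and NK cell genes 3 were higher and 9 lower (camera adjusted p = 0.425), and Nkg7, a cytotoxic granule gene, was at 8.97 ± 5.22 CPM in WT, where WT replicate 1 had 0, and 26.5 ± 8.12 CPM in CH. Of 13 mast cell, basophil and eosinophil genes 8 were higher and 5 lower (camera adjusted p = 0.738). Of 14 endothelial and stromal genes 7 were higher and 7 lower (camera adjusted p = 0.73), at a level of 1.37 ± 0.56 log2 CPM in WT and 1.38 ± 0.39 in CH. The B cell list was called lower in 7 of 24 alternatives (range 0.00109 to 0.88), among them those without WT replicate 1 (adjusted p = 0.00109, median -0.75), CH replicate 1 (adjusted p = 0.021) or CH replicate 2 (adjusted p = 0.0454). Its median was -0.28 without WT replicate 5, -0.38 without WT replicate 3 and -0.39 without CH replicate 4. Lymphoid priming genes were also called lower in 7 (range 0.00118 to 0.978), among them those without WT replicate 1 (adjusted p = 0.00118, median -0.26) or CH replicate 1 (adjusted p = 0.0252), and their median was -0.19 without CH replicate 5 and -0.21 without WT replicate 3.

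**Figure D3:**
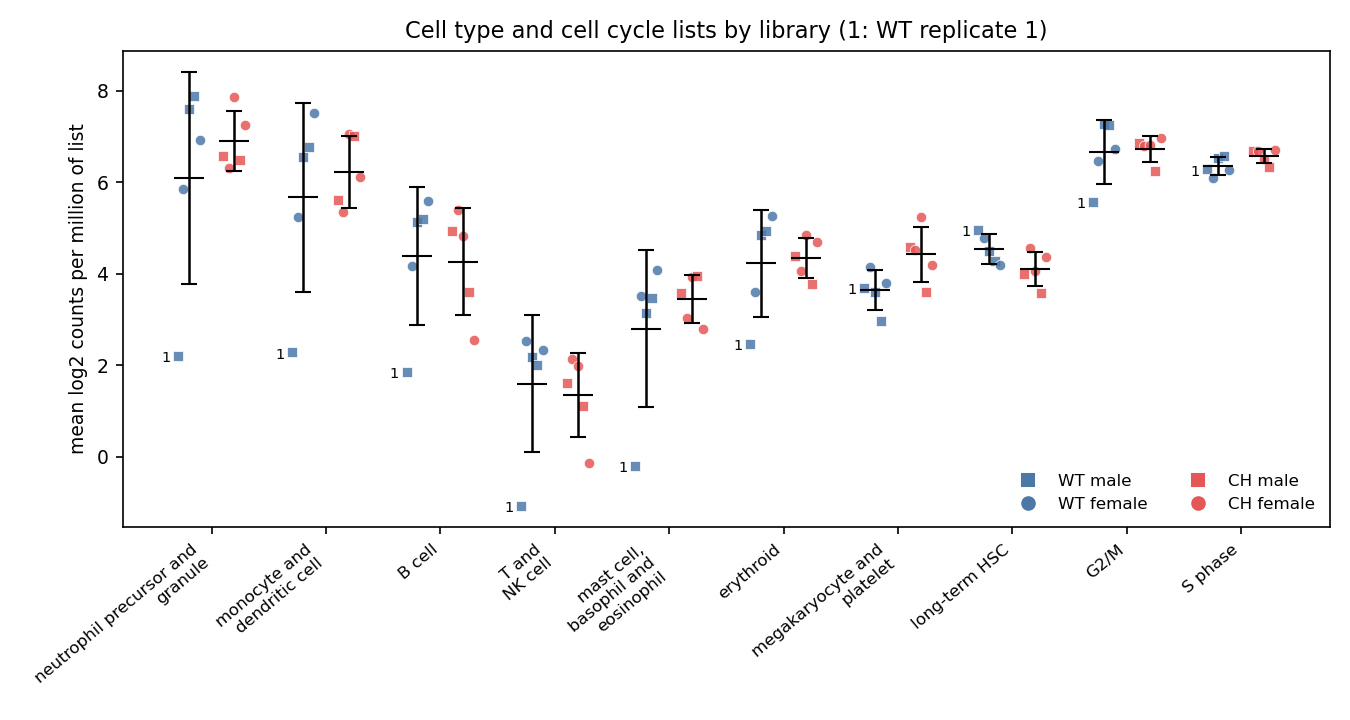
Mean level of 10 gene lists in each library, in log2 CPM, for WT (blue) and CH (red), with squares for males, circles for females, black bars for the mean with 1 SD (n = 5 each) and the digit 1 beside WT replicate 1. WT replicate 1 lies at 2.2 for neutrophil genes, where the other WT libraries lie at 5.84 to 7.88, and at 4.95 for long-term HSC genes, the highest of all libraries.

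Genes of DNA replication were higher in CH as a list. Of 32 S phase genes 29 were higher and 3 lower, with a median log2 fold change of 0.22 (camera adjusted p = 0.000381, or adjusted p = 0.676 with an estimated correlation). The level was 6.35 ± 0.2 log2 CPM in WT and 6.58 ± 0.15 in CH (SD, n = 5 each), with WT replicate 1 at 6.28. Hells, a chromatin remodeller gene, had a log2 fold change of 0.35 (SE 0.15), Mcm6, of the replicative helicase, was at 344 ± 41.9 CPM in WT and 419 ± 57.5 CPM in CH, and the replication genes E2f1 and Gins1 had log2 fold changes of 0.59 (SE 0.27) and 1.15 (SE 0.56). Only 1 of the S phase genes, Hells, had an unadjusted p under 0.05. This call ended in males alone, where the direction turned (adjusted p = 0.978), at the end of a range that began at 2.09e-08, and the median was 0.14 without WT replicate 2, 0.06 in males alone and 0.33 in females alone. For 30 genes of the G2 and M phases 12 were higher and 18 lower (camera adjusted p = 0.868), with a median of -0.06 but a level of 6.65 in WT and 6.73 in CH. This list was called in 5 of 24 alternatives (range 0.000131 to 0.984), lower without WT replicate 1 (adjusted p = 0.0079, median -0.16) but higher in females alone (adjusted p = 0.000133, interaction adjusted p = 0.000316, or adjusted p = 0.916 with an estimated correlation).

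Of 27 quiescence and cell cycle inhibitor genes 16 were lower and 11 higher, with a median log2 fold change of -0.08 (camera adjusted p = 0.00955, or adjusted p = 0.676 with an estimated correlation). The level was 4.56 ± 0.39 log2 CPM in WT, with WT replicate 1 at 3.91, and 4.25 ± 0.25 in CH (SD, n = 5 each). Cdkn1c, the gene for the inhibitor p57, was at 19.0 ± 19.4 and 6.21 ± 4.8 CPM, but WT replicate 1 held 52.7 CPM and the other WT libraries 5.03 to 17.3 CPM. Egr1, an early response factor gene linked to stem cell quiescence, was at 274 ± 108 and 164 ± 67.2 CPM, and Ndn and Nr4a1 were the 2 members at an unadjusted p under 0.05. The list was not called without WT replicate 2 (adjusted p = 0.0579) or WT replicate 4 (adjusted p = 0.0563) and in females alone (adjusted p = 0.36), within a range of 0.00218 to 0.36. The median was -0.16 without WT replicate 1 or CH replicate 5, -0.20 without CH replicate 1, -0.22 without WT replicate 5 and -0.27 without CH replicate 4. With voom it was -0.12, with quality weights -0.17, with 1 surrogate variable -0.18, with the added covariates -0.19, in males alone -0.26 and in females alone -0.02.

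Interferon response genes were lower in CH as a list, 30 of 38 members, with a median log2 fold change of -0.30 (camera adjusted p = 0.000381, or adjusted p = 0.682 with an estimated correlation). The level was 4.18 ± 0.8 log2 CPM in WT, with WT replicate 1 at 2.89, and 4.04 ± 0.34 in CH (SD, n = 5 each). Iigp1, an interferon-induced GTPase gene, was at 37.2 ± 16.3 CPM in WT and 21.1 ± 10.2 CPM in CH and was the single member with an unadjusted p under 0.05. Ifi44 was at 24.9 ± 13.9 and 12.8 ± 5.15 CPM, and the viral RNA sensor gene Ifih1 at 58.6 ± 4.06 and 47.9 ± 9.72 CPM, with CH replicate 4 at 64.6 CPM. The call was lost without WT replicate 2 (adjusted p = 0.0579) or WT replicate 5 (adjusted p = 0.0529), both female, and in males alone the direction turned (adjusted p = 0.752). The full range was 9.4e-13 to 0.752. The median was -0.15 without WT replicate 5, -0.16 without WT replicate 2, -0.19 without CH replicate 5, -0.54 without CH replicate 4, -0.47 with voom quality weights, 0.22 in males alone and -0.81 in females alone.

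Immediate early genes, which also respond to the dissociation of tissue, were lower in CH as a list, 22 of 31 members, with a median log2 fold change of -0.15 (camera adjusted p = 0.00955, or adjusted p = 0.676 with an estimated correlation). The level was 5.57 ± 0.17 log2 CPM in WT, with WT replicate 1 at 5.28, and 5.38 ± 0.52 in CH (SD, n = 5 each). Nr4a1, a nuclear receptor gene, was at 75.3 ± 21.4 CPM in WT and 47.9 ± 13.3 CPM in CH and Ier2 at 131 ± 22.0 and 98.5 ± 27.5 CPM. Fosb, of the AP-1 factor, went the other way at 5.17 ± 1.55 and 20.1 ± 17.0 CPM. CH replicate 3 held 48.4 CPM of Fosb and the other CH libraries 5.22 to 20.06 CPM. Nr4a1 and Fosb were the members at an unadjusted p under 0.05. Camera made no call without WT replicate 1 (adjusted p = 0.0575), WT replicate 4 (adjusted p = 0.0557), CH replicate 4 (adjusted p = 0.136) or CH replicate 5 (adjusted p = 0.0859) and with voom quality weights (adjusted p = 0.0941). In females alone the direction turned (adjusted p = 0.991), in a range that began at 0.000121. Their median was -0.09 without CH replicate 4, -0.10 without WT replicate 4, -0.33 without CH replicate 3, -0.34 without WT replicate 5, -0.44 in males alone and 0.05 in females alone.

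Genes of cholesterol synthesis were lower in CH as a list, 19 of 24 members, with a median log2 fold change of -0.29 (camera adjusted p = 0.00955, or adjusted p = 0.676 with an estimated correlation). The level was 4.15 ± 0.71 log2 CPM in WT, with WT replicate 1 at 2.92, and 4.1 ± 0.16 in CH (SD, n = 5 each). Sqle, the gene for squalene epoxidase, was at 27.8 ± 5.09 CPM in WT and 16.3 ± 3.56 CPM in CH without overlap and was the single member at an unadjusted p under 0.05, and Insig1, a sensor of sterols, at 31.2 ± 16.7 and 17.2 ± 6.15 CPM. Srebf2, the gene for the pathway's main transcription factor, was at 167 ± 22.4 and 143 ± 16.7 CPM. The call ended without WT replicate 2 (adjusted p = 0.0952), WT replicate 4 (adjusted p = 0.0991) or CH replicate 4 (adjusted p = 0.136) and in females alone (adjusted p = 0.856), in a range that began at 0.000269. The median here was -0.16 without WT replicate 4, -0.17 without CH replicate 1, -0.44 without WT replicate 5, -0.50 in males alone and -0.04 in females alone.

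Genes of the unfolded protein response were higher in CH as a list, 20 of 26 members, with a median log2 fold change of 0.23 (camera adjusted p = 0.0361, or adjusted p = 0.855 with an estimated correlation). The level was 6.28 ± 0.4 log2 CPM in WT, with WT replicate 1 at 5.58, and 6.5 ± 0.24 in CH (SD, n = 5 each). Calr, the gene for the chaperone calreticulin, was at 1059 ± 128 CPM in WT and 1325 ± 179 CPM in CH, and the chaperone genes Dnajc3 and Pdia4 had log2 fold changes of 0.44 (SE 0.18) and 0.38 (SE 0.17). Asns, the asparagine synthetase gene, went the other way at 48.8 ± 15.7 and 31.8 ± 16.0 CPM. Calr, Dnajc3 and Asns were the members at an unadjusted p under 0.05. The call did not hold when 1 library was left out, this being WT replicate 1 (adjusted p = 0.0529), WT replicate 2 (adjusted p = 0.322), WT replicate 3 (adjusted p = 0.0933), WT replicate 5 (adjusted p = 0.0529), CH replicate 3 (adjusted p = 0.298) or CH replicate 4 (adjusted p = 0.0709). It was also lost without an expression filter (adjusted p = 0.0574), on log2(TPM + 1) (adjusted p = 0.0557), with 1 surrogate variable (adjusted p = 0.0576), in males alone (adjusted p = 0.803) and in females alone (adjusted p = 0.09), and the range was 0.00239 to 0.803. The median was 0.14 without WT replicate 1, 0.13 with 1 surrogate variable and 0.09 with voom quality weights.

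The remaining lists were not called over all libraries. Of 52 cytosolic ribosomal protein genes 43 were higher and 9 lower, with a median log2 fold change of 0.09 (camera adjusted p = 0.116), and of 41 nuclear genes of oxidative phosphorylation 29 were higher and 12 lower, with a median of 0.09 (camera adjusted p = 0.425). All 10 tested mitochondrially encoded genes were lower, with a median of -0.10 (camera adjusted p = 0.12). Of 25 glycolysis genes 14 were higher and 11 lower (camera adjusted p = 0.738), with a median of 0.05 and a mean of -0.01. Of 26 replication-dependent histone genes 14 were higher and 12 lower (camera adjusted p = 0.725), at 7.14 ± 0.76 log2 CPM in WT, with WT replicate 1 at 6.09, and 7.26 ± 0.36 in CH. Of 27 NF-kB and cytokine genes 14 were higher and 13 lower, with a mean of -0.09 and a downward direction in camera but a median not below 0 (camera adjusted p = 0.509), and of 28 p53 target genes 18 were higher and 10 lower, with an upward direction in camera and a median of 0.08 but a mean of -0.05 (camera adjusted p = 0.868). Of 22 genes of the TGF-beta and BMP pathway 10 were higher and 12 lower (camera adjusted p = 0.284), and Tgfb1, among them, had a log2 fold change of 0.52 (SE 0.14). WT replicate 1 had 2.52 log2 CPM of NF-kB and cytokine genes against 3.65 to 4.3 in the other WT libraries, and 2.22 of p53 target genes against 3.47 to 3.82. Ribosomal protein genes were called higher in 8 of 24 alternatives (range 1.03e-10 to 0.977), among them those without WT replicate 1 (adjusted p = 0.000139, median 0.14) or CH replicate 4 (adjusted p = 2.22e-05, median 0.16), but the median was 0.035 without WT replicate 5, where the direction in camera turned, 0.032 without CH replicate 1 and 0.027 without CH replicate 2. Histone genes were called in 4 (range 4.36e-07 to 0.977), higher without WT replicate 4 (adjusted p = 0.0361) or CH replicate 4 (adjusted p = 0.00394) and in females alone (adjusted p = 4.36e-07, interaction adjusted p = 5.71e-05, or adjusted p = 0.916 with an estimated correlation), but lower with the added covariates (adjusted p = 0.0118). Mitochondrially encoded genes were called lower in 3 of 23 (range 0.021 to 0.978), among them those without CH replicate 1 (adjusted p = 0.021) or CH replicate 2 (adjusted p = 0.0464). Oxidative phosphorylation genes were called higher in females alone (adjusted p = 0.000989, in a range up to 0.839, with an interaction adjusted p = 0.000289, or adjusted p = 0.916 with an estimated correlation).

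**Figure D4:**
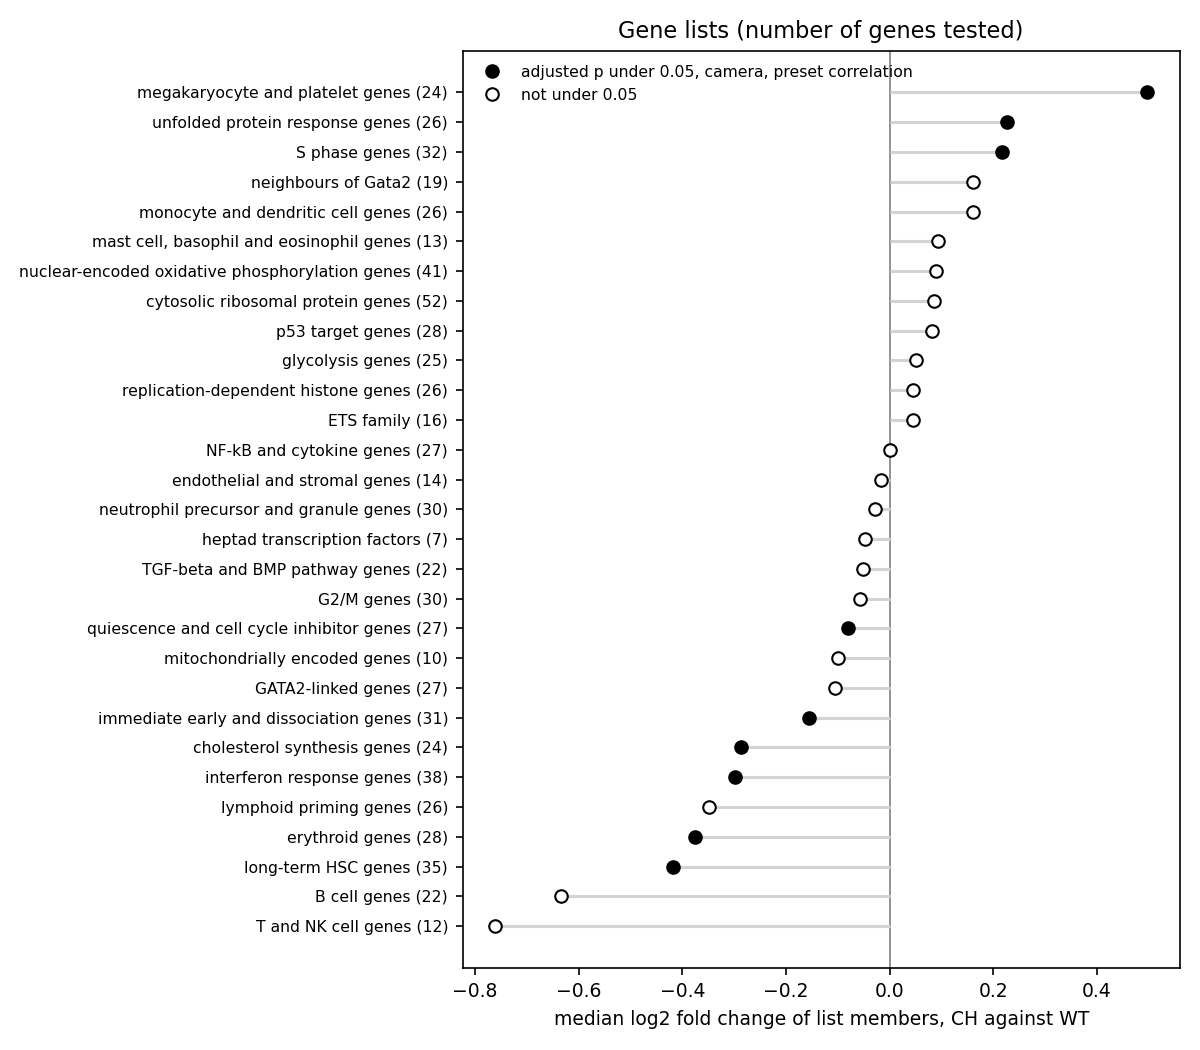
Median log2 fold change of CH against WT over the tested members of each of the 29 gene lists, whose number of tested genes stands in brackets, with filled points for lists with a camera adjusted p under 0.05 at the preset correlation. The 9 filled points run from -0.42 for long-term HSC genes to 0.50 for megakaryocyte and platelet genes, and with an estimated correlation 0 lists were called.

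The sexes were compared in the same fit to check the labels. Xist (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254), the RNA that silences an X chromosome in females, was at 1761 ± 301 CPM in females, from 1395 to 2122, and at 0.343 ± 0.766 CPM in males (SD, n = 5 each). CH replicate 4, a male, had 42 Xist counts (1.71 CPM) and the other males 0. The fitted log2 fold change of Xist, 12.55 (edgeR adjusted p = 0.00744), rests on these 42 counts and was 18.65 without CH replicate 4. Xist was the single gene called higher in females, and 0 genes were lower, with 238 genes at an unadjusted p under 0.05 (448 without WT replicate 1). DESeq2 called 6 genes higher in females, limma-voom 0 with or without quality weights, and limma on log2(TPM + 1) 3. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were at 69.8 ± 18.3, 40.3 ± 10.2, 35.9 ± 8.64 and 25.7 ± 10.4 CPM in the 5 males. The tables of females do not list these genes, and with such genes taken as 0 edgeR called 5 lower in females, these 4 and Gm47283, which was named after its values were seen. Whether the counts of both sexes rest on the same reference is not given in the sources used here, so a technical part in the values between the sexes and of the interaction was not excluded.

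Whether the difference between CH and WT itself differed between the sexes was tested with an interaction term, over 3 male and 2 female WT libraries and 2 male and 3 female CH libraries. The genes with the smallest p included Ccne1, the gene for cyclin E1, which drives entry into DNA replication, Sh2d4a, an adaptor protein gene, and Neo1, the gene for the receptor neogenin. Sh2d4a was at 11.7, 18.1 and 14.7 CPM in WT males, 0.22 and 0.29 in CH males, 7.52 and 6.14 in WT females and 5.7, 11.2 and 15.7 in CH females. Its interaction term was 6.51 on the log2 scale, that of Ccne1 was 2.97, and those of Neo1, Grk3 and Frmd4a were 11.30, -1.97 and -1.27. The value for Neo1 rests on 0 CPM in both CH males and on CH replicate 5 at 30.63 CPM. The other CH females held 4.22 and 5.46 CPM of Neo1. Each had an edgeR adjusted p of 1, and 0 genes were called, with 440 at an unadjusted p under 0.05. That number was 1093 without WT replicate 1, 667 without WT replicate 3, 277 without WT replicate 2 and 1174 with 1 surrogate variable. DESeq2 called 32 genes, among them Sh2d4a (adjusted p = 2.27e-07), Ccne1 (adjusted p = 0.0016) and Neo1 (adjusted p = 0.000701). Without WT replicate 5 edgeR called 1 gene, Gm20716 (adjusted p = 0.00489), and without CH replicate 4 it called 1, Gm42047 (adjusted p = 0.0378), both named after their values were seen.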

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

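The count of mature-cell transcripts in WT replicate 1, both tests on Rian and the splits for the long-term HSC list were chosen after the result was seen. Each level of the named genes and lists was checked within each genotype for a single library far from the other 4, in 202 groups of 5 libraries. Such a library was found in 22 groups, 12 times WT replicate 1, where chance picks out about 1 in 20 groups, or 10.

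WT replicate 1 stood apart in many values at once: its total of 14.3 M counts (29.8 to 32.9 M in the other WT libraries) was the lowest, and so were its levels of 8 lists given further on. Its lower depth is argued against as the whole cause, because the other 9 libraries thinned to its total still detected at least 22.4% more genes (13735 in the lowest, against 11223). Loss of transcripts in a library made from little RNA stays open, since of 3073 genes outside the lists with a mean of 10 to 30 CPM in the other libraries 13.2% had 0 counts in WT replicate 1 and at most 0.39% in any other library. Less RNA of mature blood cells, which the lineage-negative gate should remove, may add to this: 6 of 6 abundant transcripts were lower in WT replicate 1 than in all other libraries (S100a8 72.1 against 228 to 1460 CPM, S100a9 197 against 629 to 4060, Lyz2 147 against 905 to 3290, Elane 0 against 30.2 to 321, Mpo 57 against 173 to 1240 and Cd79a 6.34 against 17 to 94.3), while of 3490 genes outside the lists at 55.5 CPM or more 36.7% were lowest in it but 3.58% lay as far (2.67-fold) below the next library. The 6 are members of lists already seen lowest in WT replicate 1, so they are no separate support. Progenitors express Mpo and Elane as well, and no biological explanation was tested, since genotype and sex are shared with other libraries.

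Long-term HSC genes were lower in CH as a list, with a median log2 fold change of -0.42, a call that was not made with an estimated correlation (camera adjusted p = 0.676). With the levels of the neutrophil and monocyte lists as covariates the median was -0.38, which is 90.4% of its size. That lies past the bound set against more RNA of granulocytes and monocytes in the CH libraries diluting stem cell genes. The fit still cannot decide this, because both covariates lie far lowest in WT replicate 1 (2.2 and 2.28 log2 CPM). The other WT libraries lie at 5.84 to 7.88 and 5.23 to 7.52, and WT replicate 1 also has the highest level of the stem cell list. Whether 1 library carries the change stays open, because without WT replicate 1, which has the highest level of this list, 56.4% of the median was left (-0.24, and as much with 1 surrogate variable), between the bounds set for and against it, and the largest size with another library left out was -0.64. An effect of the mutated enhancer on stem cells remains a possible explanation that these data did not separate from chance. Of 100 splits, the real one included, 36 gave a median at least as large in size (real 0.418, highest other split 0.911). The split with 0.911 nearly parts the sexes while sex was a term, and gave 0.561 with genotype as the term instead.

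Rian was nearly absent in CH: WT replicate 1 was highest at 39.6 CPM with the other WT libraries at 2.36 to 10.4, and CH replicate 1 had 0.445 CPM while the other CH libraries had 0. Without WT replicate 1, 96.3% of the log2 fold change was kept, which does not decide whether this library carries it, because CH levels near 0 set the fold whichever WT library is left out. A counting artifact of a single gene is less likely than a difference of the wider transcript unit, because Meg3, an imprinted non-coding RNA gene upstream (chromosome 12, 109541001 to 109571726), was at 3.98 to 52.4 CPM in WT and 0 to 1.71 CPM in CH, its lowest WT level 2.33 times its highest CH level. Summed over libraries, Meg3 had 1938 counts in WT and 53 in CH, all in CH replicate 2, and Rian had 1410 and 14, all in CH replicate 1. The difference was picked from all genes and non-overlapping genes were no more frequent than chance, so a loss of this imprinted unit in CH is a hypothesis, and whether it follows the mutation or the descent of the animals was not tested.

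Among other genes, Wdfy1 was at 47.5 CPM in CH replicate 1 and at 18.3 to 25.1 in the other CH libraries. WT replicate 2 held 92.9 CPM of Itga2b (15.4 to 35 in the other WT libraries), 71.9 of Trpc6 (30.3 to 37.6) and 3.66 of Tspan33 (15.9 to 18.5). WT replicate 1 held 52.7 CPM of Cdkn1c (5.03 to 17.3) and 0 of Nkg7 (9.96 to 13.5). CH replicate 4 held 64.6 CPM of Ifih1 (39.3 to 46.3), and CH replicate 3 held 2857 CPM of Lyz2 (925 to 1346).

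Among lists, WT replicate 1 had the lowest WT level, in log2 CPM, of the ETS family (5.8, others 6.21 to 6.29), mast cell, basophil and eosinophil genes (-0.21, others 3.14 to 4.07), lymphoid priming genes (3.1, others 5.01 to 5.61), T and NK cell genes (-1.07, others 2 to 2.52), immediate early genes (5.28, others 5.59 to 5.71), p53 target genes (2.22, others 3.47 to 3.82), cholesterol synthesis genes (2.92, others 4.17 to 4.6) and unfolded protein response genes (5.58, others 6.42 to 6.54). CH replicate 4 was highest for neighbours of Gata2 (5.78, other CH libraries 5.43 to 5.53) and lowest for G2/M genes (6.24, others 6.79 to 6.97) and cholesterol synthesis genes (3.83, others 4.11 to 4.21).

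The difference between CH and WT differed between the sexes for 10 lists in camera at the preset correlation, and for 0 with an estimated correlation, where the lowest adjusted p was 0.868. Interferon response genes had a CH minus WT difference in mean log2 CPM of 0.46 in males and -0.89 in females (camera adjusted p = 3.05e-07). The male and female differences were 0.04 and 0.44 for S phase genes (camera adjusted p = 5.71e-05), -0.17 and 0.42 for histone genes (camera adjusted p = 5.71e-05), -0.15 and 0.26 for G2/M genes (camera adjusted p = 0.000316) and -0.78 and -0.16 for long-term HSC genes (camera adjusted p = 0.00459). For oxidative phosphorylation they were 0.01 and 0.23 (camera adjusted p = 0.000289), for ribosomal proteins -0.01 and 0.16 (camera adjusted p = 0.000289), for erythroid genes -0.01 and 0.09 (camera adjusted p = 0.00114), for immediate early genes -0.35 and -0.13 (camera adjusted p = 0.0209) and for cholesterol synthesis -0.06 and -0.15 (camera adjusted p = 0.0473). Without WT replicate 1 the male difference was 0.02 for interferon response, -0.05 for S phase, -0.76 for histone, -0.12 for oxidative phosphorylation, 0.06 for ribosomal protein, -0.71 for G2/M, -0.82 for erythroid, -0.59 for long-term HSC, -0.46 for immediate early and -0.61 for cholesterol synthesis genes, so most of these male values depend on that library. Without it 8 lists were called, 7 of them among these 10 and the neutrophil list besides (camera adjusted p = 1.29e-13), and with an estimated correlation 0 were called, the lowest adjusted p being 0.557. The calls of long-term HSC (adjusted p = 0.584), immediate early (adjusted p = 0.238) and ribosomal protein genes (adjusted p = 0.238) were lost.

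Genes listed for males alone, which entered no comparison, held 2445 counts in the lowest and 11831 in the highest male library.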

How the results depend on the processing

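The covariates of neutrophil and monocyte levels were chosen after the result was seen, and the other alternatives were planned. The 69 named genes gave 1656 log2 fold changes under the alternatives, of which 1617 kept their sign and side of the threshold, 6 became calls (in DESeq2) and 33 turned sign, so that 60 genes never did. The main fit called none of them, so keeping the side of the threshold means staying uncalled. Many were picked by a small p in the same libraries, so kept signs were likely from the start. Lists gave 753 values, of which 644 kept their side of the threshold, 60 lost the call and 49 gained one. Gata2's log2 fold change stayed positive in all fits, from 0.04 in females alone to 0.56 with voom quality weights. The median over genes of the difference in log2 fold change from the main fit was at most 0.056 in size under any alternative. Simulated genes at 10 CPM or more, changed 2-fold, were recovered in 19.4% of cases at the dispersion trend of these libraries. Changes of this size were thus mostly below the reach of the design.

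DESeq2 called 3 genes higher and 5 lower in CH, 6 higher in females and 32 with a genotype by sex interaction. Limma on log2(TPM + 1) called 1 gene higher in CH and 3 higher in females, limma-voom called 0 higher in females with or without quality weights, and with absent genes taken as 0, 5 were lower in females, which were genes listed for males alone. Interaction calls ran from 0 to 1 with a library left out. Camera called 14 lists with 1 surrogate variable, 5 in males alone, 16 with the added covariates, 0 with an estimated correlation and 5 to 13 with a library left out (5 without WT replicate 2 or WT replicate 5, 13 without WT replicate 1), and fry called 0. For the lists called over all libraries the estimated correlations, 0.06 to 0.33, lay above the preset 0.01, which raises camera's p-values. The cause of the other differences was not tested.

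Signs turned for 9 genes, none of them called between CH and WT. The log2 fold change of Zfpm1 was 0.008 with voom, 0.12 with quality weights, 0.14 with a surrogate variable, 0.079 without the sex term, 0.036 with the covariates and -0.23 to 0.16 with a library left out. Ngp, Ltf and Lyz2 were 0.25, 0.079 and 0.13 with voom, 0.37, 0.19 and 0.26 on log2(TPM + 1), 0.75, 0.43 and 0.39 in females alone, and with a library left out -0.49 to 0.30, -0.49 to 0.23 and -0.45 to 0.22. Apoe was -0.24 with quality weights, -0.52 in females alone and -0.46 to 1.25 with a library left out, and Prtn3 was -0.96 in males alone and -0.14 to 1.17 with a library left out. Acad9 was -0.24 on log2(TPM + 1), and Runx1 and Car2 were -0.061 and 0.061 in females alone. The cause was not tested.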

Other observations

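Transcripts of mature marrow cells were abundant in these libraries although the sort selects lineage-negative cells. Ngp, a granule gene of neutrophil precursors, ranged from 473 CPM in WT replicate 1 to 15317 CPM in WT replicate 4 and from 3912 CPM in CH replicate 2 to 11542 CPM in CH replicate 3. Ltf, the lactoferrin gene of the same granules, ranged from 348 to 7735 CPM over the same WT libraries and from 1639 to 5359 CPM over the same CH libraries. Apoe was highest in CH replicate 4 at 3877 CPM and in WT replicate 5 at 3067 CPM, and both of these libraries also held the highest level of Ccr3, an eosinophil chemokine receptor gene, in their genotype (487 and 294 CPM). The same held for Stab2, of the endothelial and stromal list (69.5 and 48 CPM). Prg2, an eosinophil granule gene, was at 10.5 CPM in WT replicate 5 but at 1.59 CPM in CH replicate 4, against 73.7 CPM in CH replicate 3. Which cells these transcripts came from was not tested.

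Antibody genes varied in another order. Ighm, Igkc and Jchain, which antibody-secreting cells express at high levels, were at 14397, 7012 and 4127 CPM in CH replicate 3 and at 279, 146 and 40.8 CPM in WT replicate 1. CH replicates 4 and 5 held 1294 and 1217 CPM of Ighm, and WT replicate 5 held 5985 CPM. Iglv1, which stood among the genes with the smallest p, was highest in CH replicate 1 at 61.5 CPM, followed by CH replicate 3 at 32.8 CPM.

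The test of the region around Gata2 was planned before its result was seen, and its spread was added afterwards. Since 13 of 19 listed neighbours of Gata2 were higher in CH, the mutation acting on its surroundings, or DNA carried along with it, might shift the whole region. The 13 include Acad9, which lies on chromosome 3 and is no neighbour in the mouse. Over 31 tested genes within 1 Mb of Gata2 the median log2 fold change was 0.09, 20 genes were higher and 1, Rpn1, had an unadjusted p under 0.05. This median lay at percentile 82 of 13327 runs of as many neighbouring genes across the genome. By the planned rule this went against a shift, since it lay below the bound set for that. With the genes of the region drawn again with replacement it ran from percentile 33.2 to 98.3 (95% interval), as if neighbouring genes were independent. With this spread, added afterwards, a shift of the region is neither shown nor excluded.

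Chance could not be excluded for the genes without overlap and the lists called between CH and WT. Of 100 splits of the 10 libraries into 5 and 5, the real one included, 39 gave as many genes without overlap as the real 113 (highest other split 487) and 35 called at least as many lists as the real 9 (highest other split 16). For called genes the count of 100 of 100 splits decides nothing, since the real number was 0 in edgeR, with 272 at an unadjusted p under 0.05 and the highest other split 1. Other tools called 8 (DESeq2), 1 (limma on log2(TPM + 1)) and 0 (limma-voom). At an unadjusted p under 0.05 the other splits gave a median of 290 genes, from 63 to 1785, and 55 of 100 gave at least the real 272. The split with 1785 parts the sexes except that WT replicate 1 and CH replicate 3 change places. Sex stayed a term in these fits, so this split rests largely on those libraries against others of their sex. With genotype as the term instead, the same split gave 563 genes, so 1785 is a poor measure of chance. The split with 487 sets WT replicates 1 and 2 and CH replicates 1, 2 and 4 against the rest. Whether these libraries share a structure other than genotype was not tested. For females against males 2 of 60 splits gave as many called genes as the real 1 (Xist), the real one included, which is under the 5% level. A count of 1 that another split tied cannot exclude chance for the comparison as a whole. At an unadjusted p under 0.05, 42 of 60 splits gave at least the real 238 genes, and the other splits gave a median of 319. The real split called 2 lists, against a median of 7 in the others.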
